A study of Mus musculus with 6 samples.

How the data were processed

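Total RNA of mouse embryonic stem cells, differentiated for 2 days in N2B27 medium with or without Dox, was hybridised with a biotin label to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. The authors deposited 1 linear probe set intensity per array for 45037 probe sets. The software, background correction and normalization behind these intensity values are not given in the sources used here. The 6 columns lay on a common scale, with medians between 6.24 and 6.27 after the log2 transformation, so no further normalization was applied. About 1.6% of the values of each array were exactly 1, near the lower end of the scale (the lowest was 0.59), and were kept. No Affymetrix control probe sets were among the rows. Detection calls were not used here, so dim genes were set aside by the filter alone.

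Probe sets were named from the platform annotation. Exactly 1 gene symbol was given for 34945 probe sets (18193 genes), several for 932 and none for 9160. Symbols were checked through Entrez identifiers against a RefSeq gene table of GRCm38.p6, which changed 0 of them, and 204 identifiers were not in that table. No coordinates are given, and the same table gave the order of genes along the chromosome. Each gene was represented by the probe set with the highest mean over the 6 arrays, chosen before any test. A gene was tested if that mean was above the 30th percentile of all probe sets, a signal of 19.5, which left 14188 genes. Values were transformed as log2 of the signal plus 16.

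Arrays were grouped by the labels into GemKD and uninduced control, with the experiment number from the same label. The number marks an independent experiment with its own control in the same line, so it pairs the arrays. Deviations from the group means correlated between the GemKD and control arrays of the same experiment with 0.487, 0.474 and 0.716 in experiments 1, 2 and 3. They also correlated between experiments 1 and 2 (0.42 and 0.319) and were negative between experiment 3 and the others (-0.605 to -0.491). The deviations of the 3 arrays of a group cancel out for each gene. Given the positive values within and between experiments 1 and 2, the signs of those with experiment 3 were therefore fixed. This holds for the positive value within experiment 3 as well. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), without a block in the main comparison and with the experiment as a block as the alternative. The labels state no test. Gmnn was also tested by exact permutation, for which 0.1 is the smallest two-sided p possible. Lists of genes, 24 in all, were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The estimate and its test rest on 2 residual degrees of freedom in the block fit, so a call can be lost there without any positive correlation. Of 620 list entries 576 had a probe set with 1 gene symbol before the filter. Fewer were tested, for example 17 of 39 Hox genes. The hairpins were compared by an interaction term, the experiments by correlations of their log2 ratios, and agreement in direction by the number of genes past 1.5-fold in all 3 experiments.

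The genes named were set by a rule written before the data were examined. It took Gmnn, 13 marker genes fixed in advance, the 10 leading genes in each direction with the same sign in all 3 experiments (by size of change among those past the threshold, then filled by unadjusted p), up to 4 members of each list by size of log2 fold change, and 5 genes by the p of the hairpin interaction. Genes that differed between experiments, genes next to Hprt, genes called in experiments 1 and 2 alone and probe sets without a gene name were chosen after their values were seen.

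Alternatives were the experiment block, the hairpin as a covariate, quantile normalization, no filter and a filter at the 50th percentile, the mean of all probe sets of a gene, a pseudocount of 1 or 64, no intensity trend, an estimated correlation for lists, a 2-fold limit, and leaving out each array and each experiment in turn. The block with experiments 1 and 2 alone was added after seeing the data.

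The tests were tried on simulated data made from the spread of these arrays, in 20 simulations of the GemKD and control comparison over 14188 genes with 200 changed genes each. Of genes changed 1.5-fold 17.4% were called without the block and 39.98% with it, of those changed 2-fold 51.8% and 70.8%, and of those changed 4-fold 91.1% and 93.8%. Of unchanged genes 0% and 0.02% were called. A list of 25 genes shifted by 0.2 on the log2 scale had an unadjusted p under 0.05 in 20 of 20 simulations in both fits, and an unchanged list in 1 of 20 with and 0 of 20 without the block. Simulated genes varied independently and list members were drawn at random from the brighter genes. These rates therefore do not cover lists whose members are correlated, as in the p53 response (estimate 0.393 with the block). The 3 experiments are independent cultures per the labels, of 2 cell lines. No array of Dox-treated cells without a hairpin against Gmnn was analysed here, so effects of Dox and of the knockdown are not separated by these comparisons.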

Results

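Gene expression was measured in mouse embryonic stem cells during the first 2 days of neural differentiation, with and without knockdown of Geminin. Geminin, encoded by Gmnn, binds the replication licensing factor Cdt1 and is also known to act on chromatin and transcription factors in the early neural lineage. The cells were derivatives of E14TG2a, a male embryonic stem cell line of 129P2 background, and were cultured in N2B27, a serum-free medium in which embryonic stem cells adopt neural fate. Each line carried a hairpin in a microRNA backbone (shRNAmir) against Gmnn that is switched on by doxycycline (Dox). A knockdown culture (GemKD, with 500 ng of Dox as the labels give it) and an uninduced control were grown in each of 3 independent experiments. Experiments 1 and 3 used shRNAmir 11 and experiment 2 used shRNAmir 9, in a separate line. RNA of each culture was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, giving 3 GemKD and 3 control arrays. The median probe set signal was between 59.3 and 60.9 on the 6 arrays, and the number of arrays limits the precision. Of 18193 genes with a probe set of 1 gene symbol, 14188 were tested. Each log2 value is the log2 of the signal plus 16, which understates the change of dim genes.

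The first comparison asks how far Gmnn itself was lowered. Gmnn, measured by probe set 1417506_at, had a signal of 3499 ± 50.9 (SD, n = 3) in the controls and 1308 ± 344.5 (SD, n = 3) in the GemKD arrays. GemKD carried 27.6% of the control signal in experiment 1, 48% in experiment 2 and 36.7% in experiment 3, so every array went the way of its label. The log2 fold change was -1.44 (SE 0.17, 95% interval -1.84 to -1.05), 2.72-fold lower. The 2 groups did not overlap, which gave an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow. The limma adjusted p over all genes was 0.332 when the arrays were compared without regard to experiment and 1.95e-06 with the experiment as a block (SE 0.097).

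**Figure D1:**
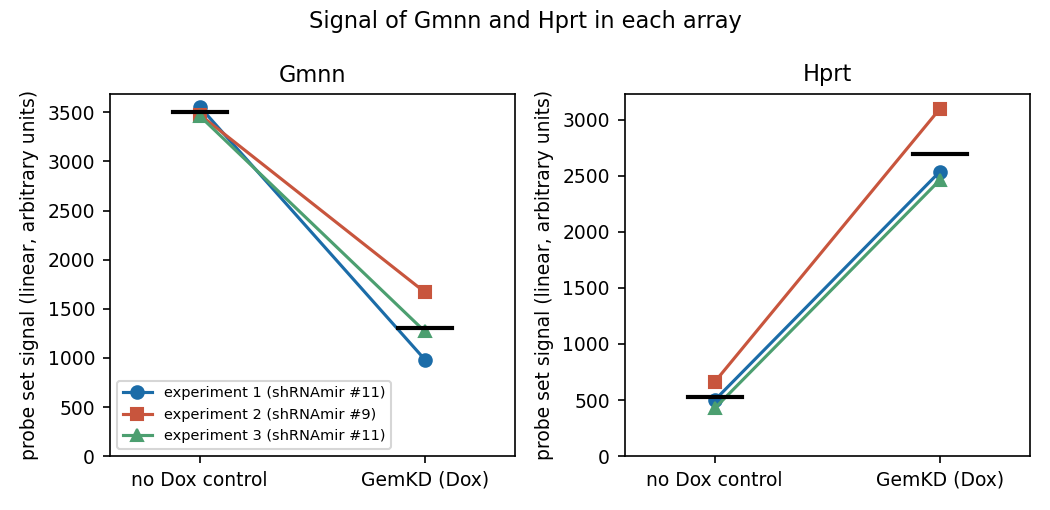
Signal (linear, arbitrary units) of the Gmnn and Hprt probe sets in the uninduced control and the Dox-induced GemKD array of each experiment; lines join the arrays of an experiment and black bars mark the means of 3 arrays. Gmnn lay between 27.6% and 48% of its control and Hprt between 468.8% and 578.2%.

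The second comparison asks which genes differed between GemKD and control after 2 days. Every GemKD array also had Dox, so a change may come from Dox or from the knockdown. Hprt, which encodes the purine salvage enzyme hypoxanthine phosphoribosyltransferase, rose from 528 ± 120.1 to 2697 ± 346.8 (SD, n = 3 per group). Its log2 fold change was 2.33 (SE 0.17, 5.04-fold), with ratios of 2.31, 2.20 and 2.49 in experiments 1, 2 and 3, and it was the 1 gene of 14188 that passed in limma (adjusted p = 0.0209; 2.14e-11 with the experiment as a block). No gene was called lower in that fit, and 123 genes had an unadjusted p under 0.05 where chance alone would give 709. That fit leaves the differences between experiments in the residual spread (SE of Sox1 0.716, against 0.059 with the block). Its p-values therefore tend to be too large, and the count of 123 does not mean fewer changes than chance. With the experiment as a block 5 genes were called, 2 higher and 3 lower, and 673 had an unadjusted p under 0.05. The 5 were Hprt and Gmnn, with Lefty1, Oscp1 and Pde1a. Over all 31526 probe sets above the filter the block fit called 3, those of Hprt and Gmnn and 1 without a gene name. Lefty1, Oscp1 and Pde1a were not called there. Lefty1, a secreted Nodal antagonist and itself a Nodal target, went from 472 ± 80.6 to 825 ± 111.8 (log2 0.79, blocked adjusted p = 0.0171), with ratios of 1.13, 0.87 and 0.37 in the 3 experiments. Pde1a, a calcium and calmodulin dependent phosphodiesterase, went from 50.7 ± 8.5 to 14.1 ± 4.6 (log2 -1.15, blocked adjusted p = 0.0379), and a dimmer probe set of Pde1a, with a mean signal of 5.7, had 0.21. Oscp1 went from 76 ± 29.6 to 22.9 ± 5.7 (log2 -1.20, blocked adjusted p = 0.0264). None of these 3 passed without the block (adjusted p = 0.9998 each).

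The genes changed at least 1.5-fold in the same direction in all 3 experiments were counted without a model. With the pseudocount of 16 there were 6, Hprt higher and Gmnn, Pde1a, Oscp1, Phxr4 and Lbp lower, against 1, 2 and 0 genes when the sign of experiment 1, 2 or 3 was turned. Gmnn is the target of the hairpins, so its place among the 6 was set by the design, and for Hprt Dox and knockdown cannot be told apart. Pde1a, Oscp1 and Phxr4 were dim, at mean control signals of 50.7, 76 and 35.4. For Lbp a second probe set, with a mean signal of 50.6 against 64.3, had a log2 fold change of -0.19 against -0.85. The count was 17 with a pseudocount of 1, 2 with a pseudocount of 64 and 3 with a filter at the 50th percentile. At 2-fold it was 3 genes, against 0 under each turned sign. The other genes that headed each direction by unadjusted p, changed the same way in all 3 experiments, did not pass. On the higher side they were Gm9725 (log2 0.77), Slc30a10 (0.53), Jup (0.45), Krt76 (0.45), Acap1 (0.43), Arglu1 (0.29), Eif4g2 (0.11) and Mtm1 (0.09). The next brightest probe sets of Slc30a10, Acap1, Arglu1, Eif4g2 and Mtm1 had 0.22, 0.02, 0.04, 0.04 and 0.07. Jup encodes plakoglobin, and its signal was 375 ± 33.6 in controls and 522 ± 70 in GemKD. On the lower side they were Atoh7 (-1.18), Opn1sw (-0.95), Phxr4 (-0.82), Gm3740 (-0.77), Pou2f2 (-0.60), Ccdc160 (-0.56) and Zdhhc23 (-0.53). Most of the lower genes were dim. Control signals of Atoh7, Opn1sw, Phxr4 and Gm3740 were 44.1, 37.2, 35.4 and 30.8, against a filter limit of 19.5, and second probe sets of Atoh7 and Opn1sw, with mean signals of 2.7 and 11.9, had log2 fold changes of 0 and 0.23. Without the block the call of Hprt was lost when any 1 array other than the control of experiment 2 was left out, with adjusted p between 0.0528 and 0.296. The median 95% half-width of a log2 fold change was 0.344 without and 0.208 with the block.

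Marker genes of pluripotency, neural fate and other lineages, chosen whatever their values, were compared next. None passed in limma with or without the block. The neural markers stayed near their controls in log2 fold change, with 0.08 for Sox1 (blocked 95% interval -0.04 to 0.21), 0.17 for Pax6 (-0.01 to 0.36), 0.03 for Zic1 (-0.19 to 0.26) and 0.04 for Nes (-0.17 to 0.24). Sox2, shared by pluripotent and neural cells, had 0.02 (-0.06 to 0.10) and the pluripotency factor Pou5f1 had -0.01 (-0.08 to 0.05). The epiblast marker Fgf5 had 0.05, the endoderm marker Sox17 -0.15 and the trophectoderm and posterior marker Cdx2 -0.12, at control signals of 89.7 and 35 for the last 2. Cdt1, the licensing factor bound by Geminin, had -0.10 (-0.18 to -0.02, blocked adjusted p = 0.921) and was lower in all 3 experiments. The p53 target Cdkn1a had -0.10 (-0.26 to 0.07). The naive pluripotency factor Nanog had the largest difference among these markers, from 1189 ± 783.3 to 1731 ± 1203 (log2 0.45, 0.29 to 0.61, blocked adjusted p = 0.0589), with ratios of 0.50, 0.62 and 0.23. No probe set of the mesoderm marker brachyury was used here.

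The large SD of some markers came from experiment 3, whose arrays stood apart in both arms. Over 7738 bright genes the SD of the log2 difference was 0.13, 0.151 and 0.138 between the arrays of experiments 1, 2 and 3, and between 0.329 and 0.373 from an array of experiment 3 to any of the others. The closest arrays of all were the GemKD arrays of experiments 1 and 2 (0.095), nearer to each other than to their own controls. Nanog averaged 2032 in the 4 arrays of experiments 1 and 2 and 315 in the 2 of experiment 3, Sox1 2318 and 550, Pax6 757 and 146, and Fgf5 127 and 621. Pou5f1 averaged 7509 and 7371.

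**Figure D2:**
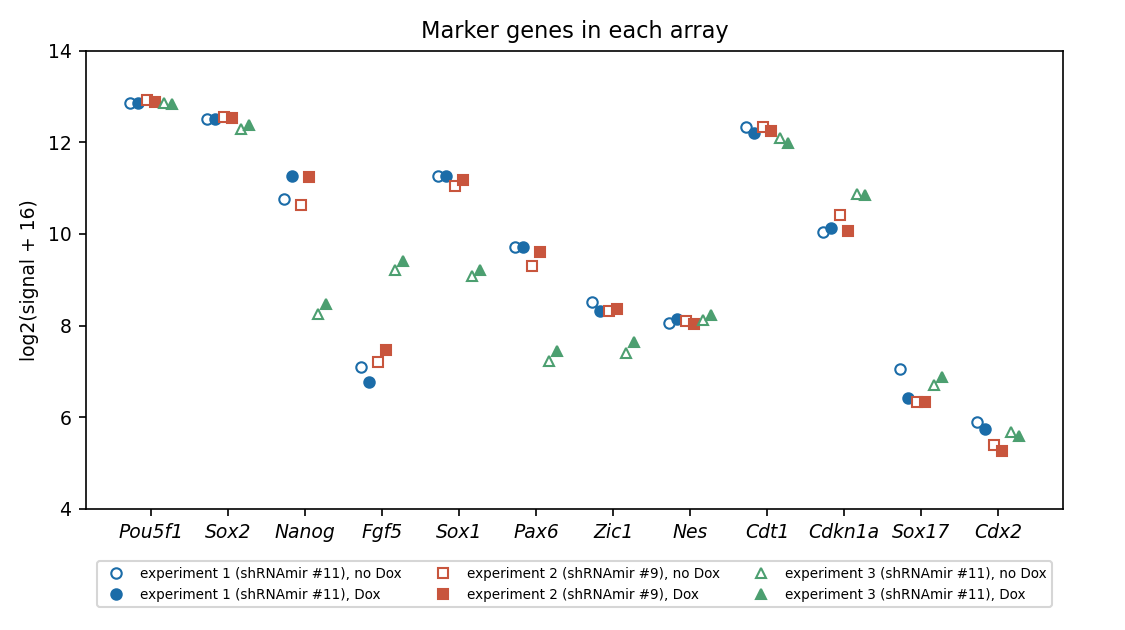
Log2 of signal plus 16 of 12 marker genes in the 6 arrays; open symbols are uninduced controls, filled symbols GemKD, and shape and colour give the experiment. Open and filled symbols of an experiment lie close together for most markers, while experiment 3 is lower in Nanog, Sox1 and Pax6 and higher in Fgf5 than experiments 1 and 2 in both arms.

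Gene lists chosen before the data were examined were then compared with all other genes by the camera test of limma, with a preset correlation between genes of 0.01. Of 24 lists, 2 were called without and 6 with the experiment as a block. With a correlation estimated for each list none was called, the smallest adjusted p being 0.354 without and 0.46 with the block. When the sign of experiment 1, 2 or 3 was turned, the block fit with the preset correlation still called 2, 5 and 5 lists. Without the block, 7 of the 10 splits of the arrays into 3 and 3, the real one among them, called at least 2 lists. A list call with the preset correlation therefore does not by itself mark a response to the knockdown. Over all genes tested, no list member passed without the block and Lefty1 was the 1 that passed with it. Adjusted over the list alone, 1 member of the BMP and Nodal targets and 0 of the other lists passed without the block. With it, 4 members of naive pluripotency, 3 of retinoic acid targets, 2 each of neural progenitor, BMP and Nodal targets and FGF and ERK feedback, and 1 of the Hox genes passed adjusted over the list alone.

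Among signalling lists, the BMP and Nodal targets were called higher in both fits with the preset correlation. All 14 tested members had a positive fold change, 3 of them higher in each of the 3 experiments, with a median log2 fold change of 0.08, and means of 0.26, 0.12 and 0.11 in experiments 1, 2 and 3 (adjusted p = 0.00269, blocked 8.35e-05; with an estimated correlation the adjusted p was 0.354 and 0.46). Lefty1 led the list, followed by the BMP target Id1 (log2 0.33, higher in 3 of 3 experiments), Lefty2 (0.30, with -0.53 in experiment 2) and Smad7 (0.28). Without the block the call was lost when the control array of experiment 1 (adjusted p = 0.112) or both arrays of that experiment (0.141) were left out. Retinoic acid targets were called with the block alone (adjusted p = 0.117 without and 9.04e-06 with it, 0.46 with an estimated correlation), with 10 of 12 members positive, 7 of them in all 3 experiments, and a median of 0.21. The blocked call was lost without experiment 2 (adjusted p = 0.1). Their means were 0.19, 0.37 and 0.09 in the 3 experiments. Hoxb1 had 0.57, the retinoid binding protein gene Crabp1 0.43, Dhrs3 0.33 and Stra8 0.32. Hox genes had means of 0.20, 0.24 and -0.09 (adjusted p = 0.751, blocked 0.029, 0.863 with an estimated correlation), and the blocked call was lost without experiment 1 (0.629) or 2 (0.736). Both lists were lower in experiment 3 as a whole, by a median of -1.24 for retinoic acid targets and -0.38 for Hox genes. Wnt targets (median 0.02, blocked adjusted p = 0.45) and FGF and ERK feedback genes (median -0.02, 0.738) were not called. Axin2, a negative regulator and target of Wnt signalling, had 0.35, with ratios of 0.49, -0.01 and 0.57 in the 3 experiments. The ERK pathway inhibitor Spry2 had 0.32, with ratios of 0.06, 0.77 and 0.13, and -0.02 in a dimmer probe set.

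Among the lists of cell state, naive pluripotency genes had a median of 0.12 and means of 0.12, 0.05 and 0.11 in the 3 experiments (adjusted p = 0.651, blocked 8.35e-05, 0.46 with an estimated correlation). Of 23 members, 12 were higher and 2 lower in all 3 experiments, and the blocked call was lost without experiment 1 (adjusted p = 0.127). Besides Nanog, the largest were Klf4 (0.27), Zfp42 (0.21, from 3222 ± 1286 to 3741 ± 1531) and Fgf4, which went the other way (-0.30). This list was lower in experiment 3 as a whole by a median of -0.83. Neural progenitor genes had 19 of 23 members positive and means of 0.08, 0.14 and 0.12 (adjusted p = 0.308, blocked 8.03e-04, 0.46 with an estimated correlation). Of these 23, 5 were higher and 1 lower in all 3 experiments, and the blocked call was lost without experiment 2 (adjusted p = 0.132). Their largest members were Olig3 (0.51, below the filter limit in both arms of experiment 3, at signals of 6.4 and 11.4), Lhx5 (0.51, at signals of 21.5 and 36.6), Cdh2 (0.28, from 745 ± 260.4 to 910 ± 321.3) and Hes3 (-0.25). Neuronal differentiation genes were not called (median 0.02, blocked adjusted p = 0.824), with Neurod1 at -0.32 and Ebf1 at 0.32. Primed epiblast genes had a median of 0.003 (blocked adjusted p = 0.424), with Pou3f1 at -0.19 and Dnmt3a at -0.13.

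Lists of other lineages were not called with or without the block, with blocked adjusted p between 0.372 and 0.738. Median log2 fold changes were -0.06 for primitive streak and mesoderm, 0.04 for endoderm, -0.06 for trophoblast, 0.003 for neural crest and surface ectoderm and -0.02 for fibroblast genes. Examples were Mesp1 (0.21), Foxa2 (0.22), Krt7 (-0.48, at signals of 40.3 and 24), Sox9 (0.52, at 16.3 and 28.5) and Col1a1 (0.34), none past the threshold.

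Genes of DNA replication and mitosis were not called. The median of 38 replication genes was 0 (SD over members 0.056, blocked adjusted p = 0.738) and that of 30 mitotic genes was -0.005 (SD 0.046, 0.738). Tyms had 0.17, Rrm1 0.11 and Orc2 -0.09. The p53 response list was called lower in both fits with the preset correlation (adjusted p = 0.0178, blocked 8.35e-05). Of its 24 members 20 were negative, 3 of them lower in all 3 experiments, and the median was -0.06. Its means were -0.01, -0.21 and 0.003 in experiments 1, 2 and 3, and the adjusted p was 0.963 and 0.869 with an estimated correlation. Plk2 (-0.32), Polk (-0.18), Apaf1 (-0.15) and Dcxr (-0.14) were its largest members. Without the block the call was lost when the GemKD array of experiment 1 (adjusted p = 0.734) or 2 (0.637), the control array of experiment 2 (0.186) or 3 (0.65), or both arrays of experiment 2 (0.792) were left out, and the blocked call was lost without experiment 2 (0.736). The list was higher in experiment 3 as a whole by a median of 0.21. The interferon, ATF4 stress, sterol synthesis, glycolysis and hypoxia, chromatin regulator, germline and two-cell stage, and imprinted gene lists were not called in either fit, with medians between -0.01 and 0.04. The interferon gene Mx1 had 0.30 and the ATF4 targets Slc7a11 and Trib3 had 0.25 and -0.12.

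**Figure D3:**
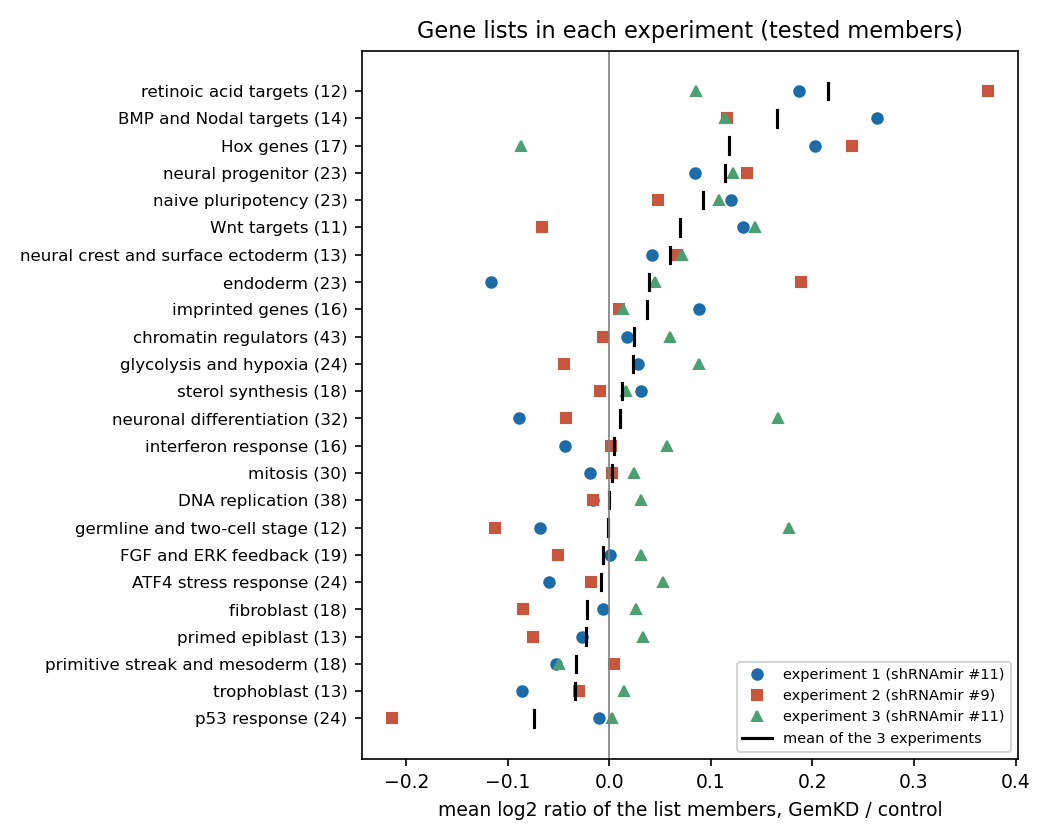
Mean log2 ratio of GemKD over control for the tested members of 24 gene lists, by experiment (symbols) and over the 3 experiments (black bars), with the number of tested members in brackets. Retinoic acid and BMP and Nodal targets lie above 0 in all 3 experiments. So do the neural progenitor, naive pluripotency, neural crest and surface ectoderm, and imprinted gene lists. The p53 response mean is -0.21 in experiment 2 and near 0 in the others.

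How alike the 3 experiments were was compared over all 14188 genes, which are not independent replicates. Pearson's r of the log2 ratios was 0.043 between experiments 1 and 2, -0.04 between 1 and 3 and 0.027 between 2 and 3, and 55.6%, 44.7% and 47.5% of genes had the same sign. In the brighter part of the genes, above the median signal, r was 0.284, -0.12 and 0.042. Because experiment 3 stood apart, the blocked fit was repeated on experiments 1 and 2 alone, a choice made after seeing the data. It called 29 genes, 16 higher and 13 lower, against 6 when the sign of experiment 2 was turned. Nanog (log2 0.56, adjusted p = 2.05e-04) and Lefty1 (0.999, 2.39e-05) were among those higher, with the retinoic acid responsive genes Crabp1 (0.60), Hoxb1 (0.71) and Stra8 (0.34) and the dorsal neural tube factor Olig3 (0.92). The neuronal factor Neurod1 (-0.59) and the epiblast and neural factor Pou3f1 (-0.30) were among those lower. Of the 27 others besides Hprt and Gmnn, Olig3 and Hoxb1 were below the filter limit in both arms of experiment 3, and 16 of the remaining 25 had the same sign there, where Nanog had 0.23, Crabp1 0.08 and Neurod1 0.22.

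The 2 hairpins were used by the study to control for effects of a single hairpin sequence. Gmnn had a log2 fold change of -1.64 with shRNAmir 11 and -1.05 with shRNAmir 9, a difference of 0.59 (95% interval -0.05 to 1.23, adjusted p = 1), and Hprt had 2.40 and 2.20. No gene differed between the hairpins in the limma interaction test. The count at an unadjusted p under 0.05 was 69, or 581 in the fit on within-experiment ratios, which also called 0 genes. The 5 genes with the smallest p were Malat1, a nuclear non-coding RNA (-0.16 with shRNAmir 11 and 0.75 with shRNAmir 9), the nucleosome remodeller Chd4 (-0.04 and 1.04), the RNA helicase Ddx6 (-0.01 and 0.81), Vwa1 (0.48 and -1.0) and Nxph4 (0.42 and -1.18), each with an adjusted p of 1. ShRNAmir 9 was represented by 1 array per arm, assumed to vary like the others, and the hairpin and experiment 2 cannot be told apart.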

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

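The tests in this part on Dox without knockdown and on the rank order of Gmnn and Hprt were chosen only after the results were seen, and the neighbours of Hprt were picked from their values. The purine gene list was tested as written before.

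Hprt rose 5.04-fold with Dox, in all 3 experiments and with both hairpins. E14TG2a is known to lack functional HPRT, and in several inducible lines derived from it the Dox-responsive cassette sits at the Hprt locus, so a candidate explanation is that Dox drove transcription there, which stays untested because 0 of the Dox-treated arrays lacked the knockdown. The 10 tested genes nearest to Hprt on the X chromosome had a median log2 fold change of -0.16, at percentile 0.06 of 13953 such windows (0.07 when the 2 lowest genes of each window are left out) and with 5 of the 10 lower in all 3 experiments. Ccdc160 had -0.56 and Fam122b -0.32, while Gpc3 (0.02), Mospd1 (-0.01) and Rtl8c (0.21) were near 0 or above, none was called over the 3 experiments (Ccdc160 and Fam122b were in experiments 1 and 2 alone), and these values decide nothing about the cause, while a wider change in purine synthesis and salvage is argued against by the median of -0.001 (SE 0.019) of 20 such genes, none of them called. A response to the loss of Gmnn stays open, because the rise of Hprt followed the fall of Gmnn with a rank correlation of 0.5 over just 3 experiments and every Dox array also carried the knockdown, so Dox and knockdown cannot be told apart.

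A probe set without a gene name, 1444856_at, lies outside the comparisons of named genes and was higher in GemKD. Its signal was 36.1 ± 8.3 (SD, n = 3) in controls and 139 ± 12.3 (SD, n = 3) in GemKD, a log2 fold change of 1.583 and 3-fold, with an adjusted p in limma of 0.170 without and 0.00104 with the experiment as a block. It was the 1 probe set of 5379 without a single gene name that was called with the block.

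Of the 24 lists, 2 (endoderm and p53 response) differed between experiment 2, the 1 experiment with shRNAmir 9, and experiments 1 and 3 in the interaction test by camera with the preset correlation, and neither did with an estimated one. With 1 array per arm the hairpin and that experiment cannot be told apart, and its arrays are assumed to vary like the others. Endoderm genes had a mean log2 ratio of -0.04 with shRNAmir 11 and 0.19 with shRNAmir 9 (adjusted p = 0.000272, but 0.936 with an estimated correlation, 21 of 23 members higher with shRNAmir 9). The p53 response had -0.004 and -0.21 (adjusted p = 0.00396, but 0.936 with an estimated correlation, 3 of 24 members higher with shRNAmir 9). The endoderm means of experiments 1 and 3, which share shRNAmir 11, were -0.12 and 0.05.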

How the results depend on the processing

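The experiment pairs the arrays, and the replicate block raised the genes called from 1 to 5, the higher ones to 2 and the lower ones to 3, and brought Gmnn (log2 -1.442) past the threshold, as well as neural progenitor (adjusted p = 0.000803), naive pluripotency (8.35e-05), Hox (0.029) and retinoic acid (9.04e-06) lists. With the block and an estimated correlation these 4 lists were lost, at adjusted p of 0.46, 0.46, 0.863 and 0.46. Among named genes the block also added Lefty1, Pde1a and Oscp1 and changed no other call. None of these 3 was called in the block fit over all 31526 probe sets above the filter. In the block fit with experiments 1 and 2 alone, chosen after seeing the data, 29 genes were called, 16 higher and 13 lower, with Gmnn at -1.445, neural progenitor at 0.00157, naive pluripotency at 0.000822, Hox at 6.92e-05, retinoic acid at 2.73e-08 and, newly, germline and two-cell stage, lower, at 0.0251, but with an estimated correlation, which leaves 1 residual degree of freedom there, no list was called (smallest adjusted p = 0.87). The cause of these differences was not tested, beyond the smaller residual spread that the block leaves.

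Without the block, the p53 response was lost with no filter (0.139), with the mean of all probe sets (0.0958) and with an estimated correlation (0.963), and the BMP and Nodal targets were lost with the mean of all probe sets (0.0958) and with an estimated correlation (0.354). The direction of both held in these. Without an intensity trend 0 genes were called and 0 were higher, Hprt having an adjusted p of 0.127 at the same fold. The genes past 1.5-fold in all 3 experiments went from 6 to 3 with a filter at the 50th percentile, to 17 with a pseudocount of 1 and to 2 with a pseudocount of 64, and a 2-fold limit gave 3. The smaller pseudocount stretches dim signals by construction. With the 50th percentile filter the correlation of log2 ratios was 0.153 between experiments 1 and 2 and -0.11 between 1 and 3. The hairpin as a covariate and quantile normalization changed no call of a named gene or list.

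Leaving out 1 array or 1 experiment gave 0 to 3 genes called and 0 to 3 higher, the 3 without experiment 3. Adjusted p values of lists ranged from 3.29e-06 to 0.792 for p53 response, 0.000991 to 0.141 for BMP and Nodal targets, 6.81e-05 to 0.948 for retinoic acid targets, 0.00133 to 0.956 for naive pluripotency, 0.0036 to 0.734 for neural progenitor, 0.000991 to 0.956 for Hox genes, 0.0303 to 0.734 for endoderm, 0.0361 to 0.995 for primed epiblast and 0.0455 to 0.995 for germline and two-cell stage genes. ATF4 stress genes ranged from 0.00116 to 0.947 and were called in opposite directions without the GemKD (0.0426) and without the control array (0.00116) of experiment 3, the reversal to higher occurring in the former. These fits had no block, so leaving out 1 array of experiment 3 puts its offset into 1 group alone. ATF4 stress genes were lower in experiment 3 (median -0.385), which gives the direction of both opposite calls. With the block this list was not called whichever experiment was left out (adjusted p = 0.95, 0.571 and 0.11). The offset also enters the lowest values of the retinoic acid, naive pluripotency and primed epiblast lists, without the GemKD array of experiment 3. The number of arrays and dim signals also limit what these values can show.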

Other observations

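In this part the distance between experiments and the correlation between list members were tested only after the results were seen, and the Y-linked and single-array genes were picked from their values.

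Experiment 3 differed from experiments 1 and 2 far more than GemKD differed from control. With the experiment as a term, 4830 genes differed between experiment 3 and the mean of the others (1691 higher, 3139 lower), and 16 between experiments 2 and 1. Naive pluripotency genes were lower in experiment 3 (19 of 23 called lower, median -0.83, adjusted p = 5.75e-11, but 0.390 with an estimated correlation), with Nanog at 2032 in experiments 1 and 2 and 315 in experiment 3, Klf4 at 401 and 95.1 and Zfp42 at 4288 and 1869. Retinoic acid targets were lower too (9 of 12, adjusted p = 1.71e-07, but 0.390 with an estimated correlation), including Stra8 (1295 and 48.9), Meis2 (2573 and 405) and Hoxb1 (190 and 6.6). ATF4 stress genes were lower (19 of 24 called, adjusted p = 4.80e-10, but 0.492 with an estimated correlation), among them Chac1 (2863 and 784) and Ddit3 (747 and 219). Primed epiblast genes were higher (7 of 13 called higher and 2 lower, adjusted p = 6.27e-05, but 0.390 with an estimated correlation). Among them were Fgf5 at 127 and 621, Otx2 at 1458 and 2759 and Pou3f1 at 3207 and 6191. Experiment 3 has 1 culture per arm.

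The Y-linked translation factor gene Eif2s3y separated the lines. Its signal was 1391 and 1474 in the 2 arrays of experiment 2 (shRNAmir 9) and between 9 and 19 in the 4 arrays of experiments 1 and 3 (shRNAmir 11). This sorts the arrays by hairpin in the way the labels do. The lines thus differ in a Y-linked gene besides the hairpin, although the parent line is male, and the comparison of hairpins cannot tell these apart. The reason for the low signal with shRNAmir 11 was not tested. Bhlhe23 had a signal of 11700 in the GemKD array of experiment 3 and at most 25.5 in the other 5 arrays.

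A difference between the 2 shRNAmir lines is argued against for the distance of experiment 3, since experiments 1 and 3 share a hairpin, and Eif2s3y at 9 to 19 fits a shared line, yet within the arm where the ratio was smaller their arrays lay 2.33 times as far apart as those of experiments 1 and 2 (2.31 after quantile normalization). Different progress from naive pluripotency to neural fate may be part of it, but it cannot be told apart from other differences here. The neural progenitor list was not called (adjusted p = 0.12) and Sox1 and Pax6 were lower in experiment 3, together with the naive genes. Medium batch, passage and date were not given in the sources used here.

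With the experiment as a block 6 lists shifted by the preset correlation, and 0 of the 6 were called with an estimated one (smallest adjusted p = 0.46). Dim probe sets are argued against as the cause of the preset calls, since 6 of the 6 were still called above the 50th percentile, while with no filter, which adds dim genes, Hox genes were lost (adjusted p = 0.369) and 5 of the 6 were called. Correlation among list members stays open, since of the 4 lists with an estimate above the preset 2 were still called when it was used as a fixed one and p53 response (adjusted p = 0.406) and Hox genes (0.296) were not, while the other 2 lists had estimates under the preset and could only stay called, and all estimates rest on 2 residual degrees of freedom. When the sign of experiment 1, 2 or 3 was turned the block fit still called 2, 5 and 5 lists but 0 genes. Genes at an unadjusted limma p under 0.05 then numbered 603, 351 and 1275, against 673 as labelled. Dependence on a single experiment met its prediction, written before, that at most 1 of the called lists would stay called. BMP and Nodal targets were the 1 of the 6 called whichever experiment was left out. Fewer arrays in those fits can also lose a call, and a response to the knockdown stays open as untested.

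The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1 gene and the highest other split 0, so 1 of the 10 reached the real count. For lists the real split called 2 and the highest other 8, and 7 of the 10 splits reached the real count. The splits that called 6 to 8 lists kept both arrays of experiment 3 on 1 side, which points to the structure of the experiments. The 3 other splits that part all 3 pairs called 1, 1 and 2 lists and 0 genes.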
